A study of Mus musculus with 13 samples.

How the data were processed

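The analysis started from the table deposited with the series, which the authors had made as log2 RPM (reads scaled to a common library total) for 25965 genes in 13 libraries. Per the labels, whole testes of adult mice were taken at 15 weeks, the outer tunica was removed, and about 2 ng of total RNA per library went into Smart-seq2 with 11 cycles of PCR. Per the labels, FastQC 0.11.8 and Trim Galore 0.6.6 were used on the reads and the genome was mm10. The aligner, the counting program and the counting strand are not given in the sources used here. Raw reads were not analysed here.

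The deposited log2 values were turned back into reads. In each library the lowest value is that of 0.9 read, given to genes without reads, and above it at least 99.96% of values in every library were whole numbers of reads (within 0.01 read). Genes at the lowest value were set to 0. The depth behind the RPM values was 4.513 to 11.126 M reads, and the listed genes held 90.4% to 95.0% of it, with a median of 6.807 M per library. Genes of the mitochondrial genome are listed at 0 in every library, so their share could not be used as a check. The libraries carry PCR copies without molecular identifiers, so the limit of 3 reads for a count of 0 (95% confidence) covers counting error only.

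The groups were set from the labels alone. Control was WT and Het together, as in the design text, and each library was taken as a separate mouse because that text counts mice. Nothing in the sources used here gives litters, batches or the meaning of the title number. These choices, with the comparisons, tests, gene lists, named-gene rule and most alternatives, were fixed before the data were examined.

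For each comparison a limma linear model with a mean-variance trend was fitted to log2(RPM + 1) in R, over genes with a mean of at least 1 RPM in the 13 libraries (16235 genes). The p-values were two-sided and adjusted by the method of Benjamini and Hochberg, with 0.05 as the threshold. Adjusted p-values of genes in all texts are from limma, whose moderated t test borrows its variance over genes, and fold changes are of RPM + 1. The unit of the table is log2, so a test made for raw counts was not the first choice, and limma-voom on the recovered reads was added as an alternative. The KO against control fit had 2 groups, KO against WT, KO against Het and Het against WT came from a fit with 3 groups, and the KO libraries of the 2 title numbers were compared in a fit in which they were separate groups beside WT and Het. Wfdc15a was also tested by a two-sided exact permutation test over all splits of the libraries. In fits with replicate number as block, KO replicates 5 and 6 have no control of their number. The KO against control difference in such fits therefore rests on KO replicates 1 to 4, of which replicates 1 to 3 are of title number 1.

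Gene lists for cell types, proteases, inhibitors, immunity and stress were written from general knowledge, 42 in all, of which 35 had at least 5 tested genes. They were tested with limma camera, a test of each list against all other genes, with its preset inter-gene correlation of 0.01. Adjusted p-values of lists are from camera over the 35 lists. Camera was also run with an estimated correlation. A count called "adjusted over the list alone" adjusts the p-values of the list's members among themselves only. The level of a list in a library is the mean of log2(RPM + 1) over its tested genes. For the comparison of somatic cell types with each other it is the median over the tested genes of log2(RPM + 1) less each gene's control mean.

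Genes were named by a rule. For KO against control it named Wfdc15a, the 12 largest rises and 12 largest falls with every library labelled KO on the same side of the control mean, up to 4 members with the lowest adjusted p of each list with called members, and 10 marker genes. For the other comparisons it named the 5 largest rises and 5 largest falls. Predicted and Rik genes were named only where fewer than 6 others were left on that side. Some genes that meet the rule are not reported here. Unless another number is given, all 6 libraries labelled KO lay on the stated side of the control mean of log2(RPM + 1) for a gene called in KO against control. The rule used the same mean. With means in RPM this does not always hold, as for C3 in KO replicate 4 (6.43 RPM against a control mean of 6.81 RPM).

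Symbols and coordinates are those of the deposited table. They were compared with GENCODE release 21 for mouse, a copy that may be another build than the one used for the table. Of 22643 shared symbols 58.5% had the same start and end and 99.6% overlapped, and the ends of Wfdc15a were identical, so its exons were read from that annotation. Genes that overlap in the table are said to do so, as the strand of counting is not known.

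The test was tried on simulated counts with the group sizes and depths of the data. For KO against control (16323 simulated genes tested) it found 30.3% of genes changed 1.5-fold, 70.3% of those changed 2-fold and 89.1% of those changed 4-fold, with 0 wrong signs and 8 unchanged genes called. For Het against WT (16360 genes) it found 16.4%, 33.3% and 69.7%, with 7 unchanged genes called. When the macrophage list was raised 2-fold, camera called it with adjusted p = 8.67e-40 and called 0 of the other lists. Simulated genes vary independently, so this does not test the preset correlation.

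Pairs of libraries within a group were compared for copies. The 24 pairs correlated at 0.952 to 0.970 and differed by 6.31 to 21.3 times the variance of counting alone, so none is a copy of another. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.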

Results

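RNA of whole testes from adult mice aged 15 weeks was sequenced in 13 libraries, and the deposited table gives 1 value for each of 25965 genes in each library. By their labels, 3 libraries came from wild-type mice (WT), 4 from heterozygotes (Het) and 6 from Wfdc15a knockouts (KO). The series' design text pools the WT and Het mice as the control group (n = 7) and compares them with the KO mice (n = 6), to ask what the gene does in spermatogenesis. The titles also carry a number whose meaning is not given in the sources used here. It is 2 for the WT libraries, 1 for Het replicate 1, 2 for Het replicates 2 to 4, 1 for KO replicates 1 to 3 and 2 for KO replicates 4 to 6. It is called the title number below.

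The reads assigned to genes came to 9.37, 7.05 and 6.62 M reads in WT replicates 1 to 3. They came to 7.42, 10.1, 6.81 and 5.64 M in Het replicates 1 to 4, and to 6.67, 7.57, 5.72, 4.22, 6.15 and 8.23 M in KO replicates 1 to 6. The mean was 7.56 ± 1.58 M (SD, n = 7) in the controls and 6.43 ± 1.42 M (n = 6) in the libraries labelled KO (two-sided exact permutation p = 0.206). Between 18583 and 19426 genes had reads in a library, and the 10 most abundant genes held 3.23% to 4.10% of its reads. At these depths 1 read was worth 0.0899 to 0.222 RPM, the unit of the table, which gives reads scaled to a common library total. A count of 0 allows up to 3 reads, which is 0.27 to 0.665 RPM depending on the library, for counting error only.

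Wfdc15a, the targeted gene, codes for a protein with a whey acidic protein domain, a fold found in several secreted protease inhibitors. In mm10 it lies on chromosome 2 from 164198863 to 164200130, on the minus strand, and the annotation gives it 1 transcript with 3 exons. Exon 1 (164199952 to 164200130) holds the start codon, exon 2 (164199658 to 164199816) holds the stop codon, and exon 3 (164198863 to 164199012) is untranslated. Its RNA was lower in the libraries labelled KO but was not lost. It stood at 65.5 ± 12.5 RPM (SD, n = 7) in the controls and at 44.6 ± 21.8 RPM (n = 6) in the libraries labelled KO, a log2 difference of -0.66 (two-sided exact permutation p = 0.0338), with 5 of the 6 below the control mean. The 2 title numbers differed. The KO libraries of number 1 held 28.1 ± 7.60 RPM (n = 3), which is -1.21 on the log2 scale against the controls (exact p = 0.00833, the smallest that 3 libraries against 7 can give). The KO libraries of number 2 held 61.2 ± 17.7 RPM (n = 3), a difference of -0.11 (exact p = 0.567). WT and Het libraries held 65.6 ± 17.6 (n = 3) and 65.5 ± 10.3 RPM (n = 4), a difference of 0.02 (exact p = 0.971).

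The gene had 156 to 869 reads per library, so depth did not limit these values. The table has 1 value per gene and library, so it cannot show from which exons the reads came, and the design of the knockout allele is not given in the sources used here. Since the level of Wfdc15a does not separate all the libraries labelled KO from the controls, they are named by their label, and every direction below is that of the libraries labelled KO against the controls. The lower level overall rests on the number 1 libraries, and the exact p rose above 0.05 when WT replicate 1 (p = 0.0714), Het replicate 2 (0.0649), Het replicate 4 (0.0541), KO replicate 1 (0.0619), KO replicate 2 (0.0821) or KO replicate 3 (0.0619) was left out. It stayed under 0.05 without any other single library and was lowest, 0.00253, without KO replicate 6 (log2 difference -0.86).

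**Figure D1:**
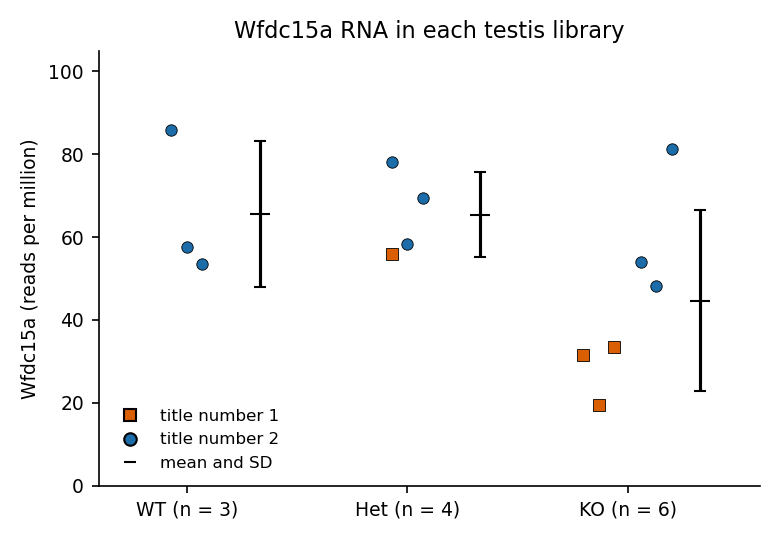
Wfdc15a in RPM in each of the 13 libraries by group, with squares for title number 1, circles for title number 2, and bars for the mean and SD of each group. The 3 KO libraries of number 1 lie between 19.4 and 33.4 RPM, under all 7 controls, and the 3 of number 2 lie between 48.1 and 81.3 RPM.

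Transcripts of late, elongating spermatids fell in the libraries labelled KO. Of the 27 tested genes of this group 22 fell and none rose (24 fell when adjusted over the list alone), with a median log2 fold change of -0.85. The protamine gene Prm1, whose product packs sperm DNA, was at 1726 ± 505 RPM in the controls (n = 7) and 730.1 ± 172 RPM in the libraries labelled KO (n = 6), which is 2.34-fold lower (log2 -1.22, SE 0.158, adjusted p = 1.66e-05). The transition protein gene Tnp1, which acts between histone removal and protamine packing, was 2.18-fold lower (log2 -1.13, SE 0.144, adjusted p = 1.59e-05). Oaz3, an ornithine decarboxylase antizyme of spermatids, stood at 2571 ± 175 RPM in the controls and 1196 ± 226 RPM in the libraries labelled KO. Spata3 fell by 1.05, Spem1 by 1.07 and Smcp, a protein of the sperm mitochondrial capsule, fell by 1.18 on the log2 scale. The mean level of the list in each of the 6 libraries labelled KO (-0.98 to -0.50 on the log2 scale, relative to the control mean) lay below all 7 controls (-0.15 to 0.12). The list was lower against all other genes (camera, adjusted p = 1.98e-26), and this call was lost with adjusted p = 0.133 with an estimated correlation.

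Of 19 tested round spermatid genes 3 fell and none rose (2 fell when adjusted over the list alone), with a median of -0.07 and camera adjusted p = 0.00101. The call was lost with adjusted p = 0.307 with an estimated correlation, and also with quantile normalization (adjusted p = 0.263, 5 fell). With median-of-ratios scaling 10 fell, with a median of -0.22 and adjusted p = 1.8e-05. The 3 were Tssk2, a kinase of spermatids (log2 -0.61, SE 0.0863, adjusted p = 4.47e-05), Tssk1 (-0.21, SE 0.0670) and Dpy19l2 (-0.22, SE 0.0783), which overlaps another listed gene. The calls of Tssk1 and Dpy19l2 were lost with title number 2 only (adjusted p = 0.0879 and 0.176), with quantile normalization (0.190 and 0.455) and without some single libraries, Tssk1 without Het replicate 1 (0.0518) or KO replicate 5 (0.0572) and Dpy19l2 without any 1 of WT replicate 1, Het replicates 1 to 4 and KO replicates 2, 3, 4 and 6 (0.0507 to 0.102). The acrosomal gene Acrv1 was at 308 ± 25.1 RPM in the controls and 306 ± 19.2 RPM in the libraries labelled KO (log2 -0.01, SE 0.0729, adjusted p = 0.953). Of 17 pachytene and diplotene spermatocyte genes none rose and 2 fell (1 when adjusted over the list alone), among them Pgk2, the testis form of phosphoglycerate kinase (log2 -0.57, SE 0.0878, adjusted p = 9.91e-05), and the list had a mean of -0.05, a median of 0.00 (-0.15 with median-of-ratios scaling) and adjusted p = 0.0908 downward. The list was called lower with median-of-ratios scaling (4 fell, adjusted p = 0.0173), with replicate number as block (0.0246) and with the KO libraries of number 1 alone (0.0321). It was not called with quantile normalization (2 rose and 3 fell, 0.958), with the KO libraries of number 2 alone (0.389, where the median was 0.07), with title number 2 only (0.458) or with an estimated correlation (0.418). Of 20 early meiotic genes 2 rose and 1 fell (1 and 1 when adjusted over the list alone). Their median was 0.09 while camera pointed down (adjusted p = 0.610), and with median-of-ratios scaling the median was -0.05, none rose and 4 fell (none and 3 with quantile normalization). Sycp3, of the synaptonemal complex, was at 108 ± 15.6 RPM in the controls and 124 ± 16.3 RPM in the libraries labelled KO (log2 0.20, adjusted p = 0.177), and it overlaps another listed gene.

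Among 10 tested genes of differentiating spermatogonia 3 rose and none fell (3 when adjusted over the list alone), and the list was not called (adjusted p = 0.147). They were Kit, the stem cell factor receptor (45.2 ± 11.2 RPM against 105.6 ± 25.7 RPM, log2 1.21, SE 0.161, adjusted p = 2.29e-05), the cyclin gene Ccnd2 (log2 1.19, SE 0.245) and Stra8, which is needed for entry into meiosis (log2 0.84, SE 0.205). Of 14 genes of undifferentiated spermatogonia 1 rose and 1 fell (none when adjusted over the list alone). Their median was 0.21, with camera pointing down (adjusted p = 0.526), and -0.02 with quantile normalization, where none rose and 2 fell. None of 17 sperm axoneme genes changed (none when adjusted over the list alone), and their median was 0.01, their mean -0.01 and their adjusted p = 0.162 downward, with a median of -0.14 under median-of-ratios scaling. With that scaling 3 fell and the list was called lower (adjusted p = 0.0182), as it was with replicate number as block (0.0253) and with the KO libraries of number 1 alone against all controls (0.0203). It was not called with quantile normalization (none fell, median 0.04, adjusted p = 0.489), with the KO libraries of number 2 alone (0.837), with title number 2 only (0.940) or with an estimated correlation (0.587).

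Sertoli and Leydig cell genes rose. Of 24 tested Sertoli cell genes 16 rose and none fell (18 when adjusted over the list alone), with a median of 0.69 and camera adjusted p = 6.37e-06 (adjusted p = 0.307 with an estimated correlation). The median was 0.87 with the KO libraries of number 1 alone, where 16 rose. It was 0.54 with those of number 2 alone, where 7 rose, and with title number 2 only 4 rose. Clu, the secreted chaperone clusterin, was at 1403 ± 344 RPM in the controls and 2822 ± 518 RPM in the libraries labelled KO (log2 1.02, SE 0.132, adjusted p = 1.75e-05). Sox9, a transcription factor of Sertoli cells, rose by 0.97 (SE 0.203), Wt1 by 0.87 (SE 0.132) and the tight junction gene Cldn11 by 0.92 (SE 0.152) on the log2 scale. Of 17 Leydig cell genes 11 rose and none fell (12 when adjusted over the list alone), with a median of 0.94 and camera adjusted p = 0.000106 (adjusted p = 0.307 with an estimated correlation). The steroid enzyme gene Cyp17a1 went from 1235 ± 205 to 2356 ± 356 RPM (log2 0.94, SE 0.104, adjusted p = 4.74e-06). Hsd17b3, which makes testosterone, was 3.19-fold higher (log2 1.67, SE 0.205), and Star, which brings cholesterol into mitochondria, was 1.84-fold higher (log2 0.88, SE 0.189). The hormone gene Insl3 went from 994 ± 340.0 to 2889 ± 1093 RPM (log2 1.54, SE 0.213), and it overlaps another listed gene.

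Some enzymes of the synthesis of cholesterol, the precursor of testosterone, also rose. Of 19 tested genes 9 rose and none fell (11 when adjusted over the list alone), with a median of 0.44 and camera adjusted p = 0.00417 (adjusted p = 0.307 with an estimated correlation). Among them Nsdhl rose by 0.73 (SE 0.123), Hmgcs1 by 0.49 (SE 0.108) and Cyp51 by 0.46 (SE 0.0859) on the log2 scale.

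Macrophage and innate immune genes also rose in the libraries labelled KO. Of 19 tested macrophage genes 13 rose and 1 fell (14 and 1 when adjusted over the list alone), with a median of 0.85 and camera adjusted p = 0.00102 (adjusted p = 0.342 with an estimated correlation). The median was 1.16 with the KO libraries of number 1 alone, where 13 rose, and 0.62 with those of number 2 alone, where 4 rose. Lyz2, the lysozyme of myeloid cells, went from 27.8 ± 8.07 to 70.0 ± 25.1 RPM (log2 1.27, SE 0.197, adjusted p = 0.000108). The complement gene C1qa rose by 1.32 (SE 0.215) and the signalling adaptor Tyrobp by 1.37 (SE 0.232) on the log2 scale. Aif1, also on the list, went against it and fell by 0.62 (SE 0.0735, adjusted p = 7.71e-06), from 382 ± 15.9 to 249 ± 26.6 RPM. Its control level was far above the 27.8 RPM of Lyz2, and whether its RNA came from macrophages was not tested. Cd68, a lysosomal protein of macrophages, was at 4.799 ± 2.15 RPM in the controls and 9.08 ± 4.88 RPM in the libraries labelled KO (log2 0.72, SE 0.346, adjusted p = 0.137). It was at 13.3 RPM in number 1 and 4.86 RPM in number 2. It passed with replicate number as block (log2 1.28, adjusted p = 0.00232) and with the KO libraries of number 1 alone (1.40, 0.00616). The block difference rests on KO replicates 1 to 4, so the 2 settings largely share their KO libraries. Ptprc, the common leukocyte antigen, was at 0.665 ± 0.830 and 1.90 ± 1.91 RPM (log2 0.61, adjusted p = 0.293). Tnf was too low to test, at 0.0600 ± 0.159 RPM in the controls and 0.234 ± 0.572 RPM in the libraries labelled KO. Both means are under the level of 3 reads, and the KO mean comes from replicate 1 alone, at 1.401 RPM.

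Of 16 complement genes 10 rose and 1 fell (11 and 1 when adjusted over the list alone), with a median of 1.17 and camera adjusted p = 0.0265 (adjusted p = 0.418 with an estimated correlation). C3, the central complement protein, went from 6.81 ± 5.10 to 33.3 ± 21.5 RPM (log2 2.16, SE 0.475, adjusted p = 0.00231), and Masp1, a protease of the lectin pathway, from 3.45 ± 2.92 to 18.5 ± 7.76 RPM (log2 2.37, SE 0.405, adjusted p = 0.000272). C7 rose by 1.13 (SE 0.197), properdin (Cfp) by 1.77 (SE 0.353) and the C1 inhibitor gene Serping1 by 1.19 (SE 0.25) on the log2 scale. The median of the list was 1.76 in number 1 and 0.59 in number 2. With the KO libraries of number 2 alone against all controls the list had adjusted p = 0.243, and the call also ended without KO replicate 1 (adjusted p = 0.0639), KO replicate 2 (0.0566) or Het replicate 2 (0.0603).

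Of 18 interferon-stimulated genes 8 rose and none fell (8 when adjusted over the list alone), with a median of 0.62 and camera adjusted p = 0.0152 (adjusted p = 0.307 with an estimated correlation). Xaf1 rose by 1.14 (SE 0.279) and the immunoproteasome gene Psmb8, which overlaps another listed gene, by 0.95 (SE 0.259). Psmb8 was at 4.25 to 7.01 RPM in the KO libraries of number 1 and at 9.53 to 11.99 RPM in those of number 2. The controls held 2.02 to 5.78 RPM, so its rise lay mostly in number 2. With median-of-ratios scaling 5 rose and with quantile normalization 2, and the list call ended with the KO libraries of number 1 alone (adjusted p = 0.0643). Of 21 genes of the response to TNF and NF-kB 12 rose and none fell (12 when adjusted over the list alone), with a median of 0.47 and camera adjusted p = 0.0214 (adjusted p = 0.342 with an estimated correlation). The TNF receptor genes Tnfrsf1a and Tnfrsf1b rose by 1.12 (SE 0.175) and 1.48 (SE 0.284), and the necroptosis kinase gene Ripk3 by 1.34 (SE 0.218). With median-of-ratios scaling 6 of the 21 rose and 1 fell, and with quantile normalization 7 rose and 1 fell.

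The series' title names proteases, and their genes and those of their inhibitors moved in both directions. Of 11 tested cathepsins, lysosomal proteases, 10 rose and none fell (10 when adjusted over the list alone), with a median of 0.94 and camera adjusted p = 3.18e-05 (adjusted p = 0.307 with an estimated correlation). Ctsd went from 150.1 ± 32.9 to 285 ± 29.6 RPM (log2 0.94, SE 0.118, adjusted p = 1.35e-05) and Ctsb from 131 ± 36.5 to 255 ± 54.6 RPM (log2 0.97, SE 0.147). Ctsa rose by 1.14 (SE 0.170) and Ctsz by 1.16 (SE 0.175), and all 4 overlap another listed gene.

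Of 40 trypsin-like serine proteases 6 rose and 7 fell (7 and 7 when adjusted over the list alone). Their median was -0.09 and their mean 0.06, while camera put the list below other genes (adjusted p = 0.0214, and adjusted p = 0.307 with an estimated correlation). The call also ended with title number 2 only (adjusted p = 0.0565). Fry, a test without other genes as reference, gave adjusted p = 0.351, which does not bear on the difference from other genes. The secreted protease gene Htra1, which overlaps another listed gene, went from 21.7 ± 11.4 to 65.9 ± 10.9 RPM (log2 1.70, SE 0.240, adjusted p = 4.15e-05), and Prss35 went from 15.2 ± 2.35 to 50.2 ± 24.8 RPM. Prss58 went from 134 ± 11.0 to 78.0 ± 19.4 RPM (log2 -0.80, SE 0.124, adjusted p = 0.000107), and Prss39 fell by 0.36 (SE 0.0634). In 13 kallikreins, another branch of this family, none rose and 1 fell (1 when adjusted over the list alone). It was Klk1b8 (log2 -1.21, SE 0.191), and the median of the list was 0.19, its mean -0.04 and its adjusted p = 0.0689 downward, with a median of -0.04 under quantile normalization. The list's median was -0.50 in the KO libraries of number 1 and 0.37 in those of number 2, and number 1 alone gave adjusted p = 0.0138 downward. With median-of-ratios scaling 3 kallikreins fell and with quantile normalization 4.

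Of 29 ADAM metalloproteases 5 rose and 2 fell (5 and 2 when adjusted over the list alone). The shedding enzymes Adam10 and Adam17 rose by 0.98 (SE 0.146) and 0.78 (SE 0.166), and Adam21 fell by 0.58 (SE 0.131). Adam17 overlaps another listed gene. The median was -0.02, the mean 0.17 and the list was not called (adjusted p = 0.349, downward), and with median-of-ratios scaling 4 rose and 5 fell. Of 7 matrix metalloproteases 4 rose and none fell (4 when adjusted over the list alone, list adjusted p = 0.228), among them Mmp14 (log2 1.02, SE 0.206) and Mmp23 (1.70, SE 0.280). With median-of-ratios scaling 3 rose and 1 fell. The mean RPM level of this list was 0.50 to 0.99 above the control mean in the libraries labelled KO, and the highest control was at 0.28. Camera did not place the list above other genes. Of 19 ADAMTS proteases 2 rose and none fell (none when adjusted over the list alone, list adjusted p = 0.849).

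Among protease inhibitors, 9 of 22 tested serpins rose and none fell (9 when adjusted over the list alone, list adjusted p = 0.134). The list was called higher with median-of-ratios scaling (adjusted p = 0.0321), quantile normalization (0.0316) and the KO libraries of number 1 alone (0.0203). It was not called with those of number 2 alone (0.550), with replicate number as block (0.0692) or with an estimated correlation (0.587). Serpina5, the protein C inhibitor, went from 154 ± 48.6 to 366 ± 118 RPM (log2 1.23, SE 0.196, adjusted p = 0.000135) and Serpina3n rose by 1.75 (SE 0.332). Of 26 other protease inhibitors 12 rose and 4 fell (13 and 4 when adjusted over the list alone, list adjusted p = 0.758), and with median-of-ratios scaling 9 rose and 7 fell. The cystatin gene Cst8 was among those that fell (log2 -0.69, SE 0.115). Of 6 tested genes of the WFDC family other than Wfdc15a 3 rose and none fell (3 when adjusted over the list alone, list adjusted p = 0.446). They were Wfdc1 (18.8 ± 3.46 against 42.0 ± 14.4 RPM, log2 1.06, SE 0.201, adjusted p = 0.000674), Wfdc10 (log2 0.99, SE 0.245) and Wfdc9 (log2 0.86, SE 0.243), and the last pair overlap each other. With median-of-ratios scaling 3 rose and 1 fell, and with quantile normalization 2 rose and 1 fell and Wfdc9 lost its call (adjusted p = 0.0898). Wfdc9 and Wfdc10 also lost theirs with title number 2 only (0.242 and 0.155). Of 28 tested neighbours of Wfdc15a on chromosome 2, a list that shares Ctsa, Wfdc9 and Wfdc10 with those above, 8 rose and 1 fell (9 and 2 when adjusted over the list alone, list adjusted p = 0.652). The proteoglycan gene Sdc4 rose by 0.90 (SE 0.147), and the list's median of 0.11 was -0.03 with median-of-ratios scaling, where 6 rose and 3 fell (5 and 4 with quantile normalization).

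**Figure D2:**
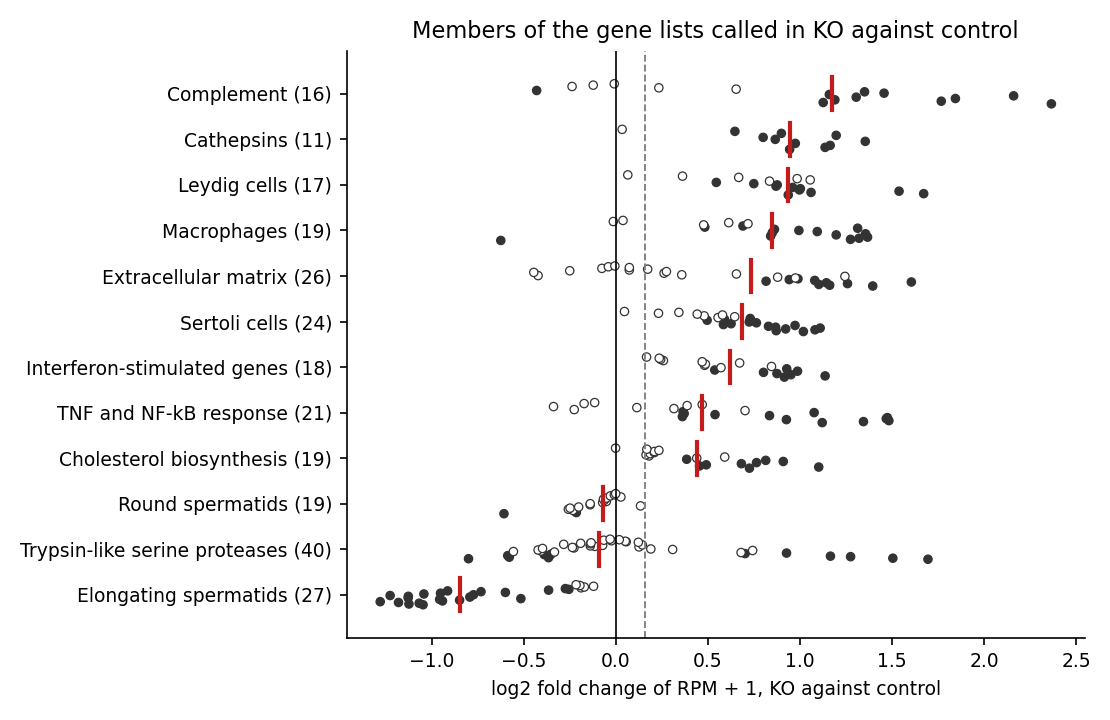
Log2 fold changes of RPM + 1, libraries labelled KO against control, of the tested members of each of the 12 lists called by camera, with the number of tested members in parentheses. Filled points passed adjusted p 0.05 over all genes, red lines are list medians and the dashed line is the median of all genes, 0.16, which is 0.02 with median-of-ratios scaling. The elongating spermatid list lies at a median of -0.85, the lists from cholesterol synthesis to complement at 0.44 to 1.17, and the trypsin-like list has a median of -0.09 but a mean of 0.06.

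Some extracellular matrix genes rose as well. Of 26 tested genes 10 rose and none fell (13 when adjusted over the list alone), with a median of 0.74 and camera adjusted p = 0.0373 (adjusted p = 0.370 with an estimated correlation). The collagen gene Col3a1 rose by 1.40 (SE 0.183), the proteoglycan gene Dcn by 1.10 (SE 0.162), and Sparc went from 389 ± 116 to 861 ± 198 RPM (log2 1.16, SE 0.162, adjusted p = 3.63e-05). The call ended with the KO libraries of number 2 alone against all controls (adjusted p = 0.0541), without KO replicate 2 (0.0566) and without KO replicate 5 (0.0566).

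The single gene with the largest rise was Timp1, an inhibitor of matrix metalloproteases on chromosome X (20870166 to 20874735). It went from 2.89 ± 3.86 to 26.7 ± 9.79 RPM (log2 3.24, SE 0.432, adjusted p = 2.29e-05), and it lies inside Syn1 (20860511 to 20921004), whose value rose with it (log2 3.12, SE 0.414). Without the counting strand the reads of this pair cannot be told apart. The controls were not alike for Timp1, with 9.92 and 6.86 RPM in WT replicates 2 and 3 and 0.55 to 1.01 RPM in the others. KO replicate 4, the lowest of the libraries labelled KO, held 11.7 RPM. Lrg1, a secreted glycoprotein of inflammation, went from 14.9 ± 13.3 to 72.4 ± 30.2 RPM (log2 2.46, SE 0.406), the actin-binding calponin gene Cnn3 from 9.52 ± 6.10 to 46.1 ± 17.8 RPM (log2 2.26, SE 0.315) and the transglutaminase gene Tgm2 from 25.7 ± 13.01 to 98.4 ± 23.6 RPM (log2 2.00, SE 0.236, adjusted p = 7.71e-06). Hspb8, Robo4, Ramp1 and Col18a1 rose by 1.94 to 2.05, and Tgm2 and Col18a1 overlap another listed gene. The largest falls were of Olfr733, an olfactory receptor gene (8.10 ± 1.62 against 1.60 ± 0.975 RPM, log2 -1.86, SE 0.246, adjusted p = 2.17e-05), Gm12970 (log2 -1.55, overlapping another listed gene), Gm498 (239 ± 45.7 against 85.8 ± 20.6 RPM, log2 -1.48, SE 0.147) and Tppp2 (73.3 ± 12.4 against 26.3 ± 6.58 RPM, log2 -1.46, SE 0.144). The next were 4931408A02Rik, 1700012A03Rik, AC113312.1, 9230104L09Rik, 1700080E11Rik, Tnni3k, Cd33 and 1700062I23Rik, which overlaps another listed gene, at -1.45 to -1.34.

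In all, 3997 of the 16235 tested genes changed between control and the libraries labelled KO (limma with Benjamini-Hochberg adjustment), of which 2994 rose and 1003 fell. By at least 1 on the log2 scale, 617 rose and 97 fell. Every library labelled KO lay above every control for 822 genes and below for 470, where chance gives 0.117% of genes. The share of rises depended on the scaling. It was 74.9% in RPM as deposited, where the median of all genes was 0.16 on the log2 scale. With median-of-ratios scaling the median was 0.02, and 1712 genes rose and 1716 fell (49.9% rises), among them all 1003 falls and 1712 of the rises above. With quantile normalization the median was -0.01, and 1460 rose and 1532 fell (48.8%). Relative to all genes the 12 called lists kept their directions with median-of-ratios scaling, with medians such as 0.54 for Sertoli cells, 0.78 for Leydig cells, 0.71 for macrophages and 0.79 for cathepsins. In the libraries with title number 2 alone, 3 KO against 6 controls, 1549 genes changed (895 rose and 654 fell), of which 1455 were among the 3997.

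**Figure D3:**
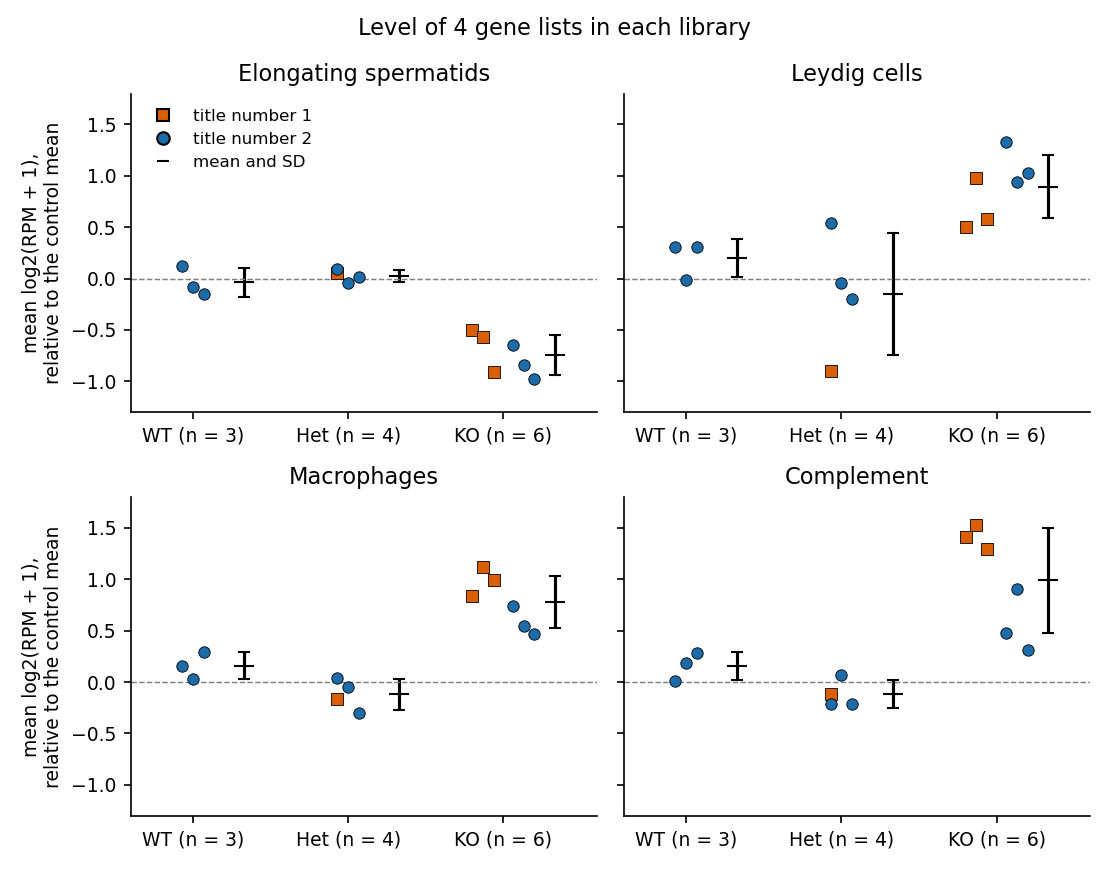
Mean log2(RPM + 1) of 4 gene lists in each of the 13 libraries, relative to the mean of the 7 controls, with squares for title number 1, circles for title number 2, and bars for the mean and SD of each group. The elongating spermatid list lies between -0.98 and -0.50 in the libraries labelled KO, and the complement list reaches 1.53 in the KO libraries of number 1 with its lowest KO value, 0.31, in number 2.

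Against the WT libraries alone, the libraries labelled KO again had higher Masp1 (3.31 ± 3.46 RPM in WT, n = 3, log2 2.38, SE 0.525, adjusted p = 0.00786) and Timp1 (log2 2.33, SE 0.452, adjusted p = 0.00329). The other large rises were of the mitochondrial magnesium channel gene Mrs2 (19.98 ± 26.2 RPM in WT and 69.0 RPM in KO, log2 2.53, SE 0.657), the matrix glycoprotein gene Emilin2 (log2 2.32, SE 0.709) and podoplanin, Pdpn (log2 2.17, SE 0.627). Mrs2 was at 55.5 ± 34.1 RPM in Het, Emilin2 at 8.97 ± 9.84 RPM and Pdpn at 1.58 ± 1.72 RPM. Emilin2 was at 18.6 RPM in the KO libraries of number 1 and 6.64 RPM in those of number 2, and Pdpn at 12.9 and 1.96 RPM. The WT libraries are all of title number 2, while the libraries labelled KO are of both numbers. The largest falls were of Olfr733 (-1.85), Tnni3k (-1.85), 4931408A02Rik (-1.71), Gm12970 (-1.60) and the tropomodulin gene Tmod4 (-1.59, SE 0.326). In all 1525 genes changed, of which 982 rose and 543 fell (64.4% rises). With median-of-ratios scaling 444 rose and 796 fell (35.8%), and with quantile normalization 423 rose and 611 fell (40.9%). The count depended on single WT libraries, with 454 genes without WT replicate 1 and 936 without WT replicate 2.

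Against the Het libraries, the largest rises were of Timp1 (0.716 ± 0.202 RPM in Het, n = 4, log2 3.92, SE 0.412, adjusted p = 3.97e-06), the overlapping Syn1 (3.85, SE 0.370), 4930486L24Rik (3.24, SE 0.424), Lrg1 (6.99 ± 2.71 RPM in Het, log2 3.14, SE 0.376) and the small heat shock protein gene Hspb8 (2.82, SE 0.570). The largest falls were of Olfr733 (-1.87), Gm12970 (-1.51), Tppp2 (-1.49), Gm498 (-1.46) and the muscle gene Xirp1 (-1.42, SE 0.403), which overlaps another listed gene, as does Gm12970. In all 3584 genes changed, of which 2748 rose and 836 fell (76.7% rises). With median-of-ratios scaling 1633 rose and 1543 fell (51.4%), and with quantile normalization 1347 rose and 1300.0 fell (50.9%). Whether KO differs more from Het than from WT was not tested apart from the comparison of Het with WT.

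No gene passed the test between Het and WT (limma, 0 of 16235 genes, lowest adjusted p = 0.180). At an unadjusted p under 0.05 there were 957 genes, where chance gives 812, and limma-voom on the recovered reads also called 0 genes. In simulated data of these groups the test found 69.7% of genes changed 4-fold and 33.3% of those changed 2-fold, so smaller differences between Het and WT could be missed. Without WT replicate 1 there were 3 genes, all lower in Het.

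Between the KO libraries of the 2 title numbers, the chemokine gene Ccl8 was at 19.0 ± 5.41 RPM in number 1 (n = 3) and 1.93 ± 2.28 RPM in number 2 (n = 3), a log2 difference of -3.00 (SE 0.444, adjusted p = 0.00381), against 0.963 ± 0.398 RPM in the controls. The growth factor gene Gdf9 (6.99 ± 4.18 against 0.0383 ± 0.0663 RPM), Afap1l2 (11.6 ± 2.51 against 1.34 ± 1.07 RPM) and Pdpn (12.9 ± 2.11 against 1.96 ± 1.65 RPM) were also lower in number 2. Higher in number 2 were Bpifb5 (1.42 ± 0.727 in number 1 against 29.6 ± 14.5 RPM, log2 3.61, SE 0.784, adjusted p = 0.04999), Olfr1188 (0.0467 ± 0.0809 against 7.76 ± 3.71 RPM), the kallikrein gene Klk1b16 (1.45 ± 0.123 against 15.8 ± 6.60 RPM), Tpbg (0.800 ± 1.25 against 9.04 ± 2.61 RPM, overlapping another listed gene) and the neuromedin receptor gene Nmur1 (0.815 ± 0.661 against 7.08 ± 2.19 RPM). Wfdc15a itself was 1.10 higher on the log2 scale in number 2 (SE 0.229, limma adjusted p = 0.0412), while the exact permutation test of 3 against 3 gave p = 0.1, the smallest it can give. In all 56 genes differed, of which 25 were higher and 31 lower in number 2. The count depended on every library, with 27, 11, 18, 29, 18 and 27 genes when KO replicates 1 to 6 were left out in turn, and on the pseudocount (23 genes with 0.25) and the filter on low values (20 genes with none). In a principal component analysis the first component (31.1% of the variance) parted the 6 libraries labelled KO from the 7 controls. On it WT replicates 2 and 3 (-11.9 and -13.2) lay between the other controls (-39.3 to -26.6) and the libraries labelled KO (15.7 to 48.3). The second (9.93%) placed Het replicate 1 (-31.5) beside the number 1 KO libraries (-22.8 to -16.1), with the number 2 KO libraries at 25.1 to 27.0 and the other 6 controls at -3.35 to 5.22.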

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

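The tests of mislabelling, of the Wfdc15b paralog and of the allele, the pair of tests on the lists called higher and the pair on the KO libraries of the 2 title numbers were chosen after the results they concern had been seen. The rule for outlying values was fixed before the data were examined.

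The mean of Wfdc15a RNA in the KO libraries of title number 2 was near that of the controls. KO replicates 4 to 6 held 54.1, 48.1 and 81.3 RPM, and the controls held 53.5 to 85.8 RPM. The highest elongating spermatid score of these 3 libraries was still 0.50 below the lowest control score (difference -0.50 on the log2 scale). This is far outside the SD of the controls of 0.098, so a swap with mice like these controls does not explain the Wfdc15a level. The score does not read the genotype, so mislabelled mice with an intact gene and a low score for another reason cannot be excluded. The level of the paralog Wfdc15b was 0.0626% of that of Wfdc15a in these libraries. Reads of Wfdc15b that were counted to Wfdc15a would not show in that level, and the counting program is not given, so shared reads cannot be excluded. A knockout allele that still gives RNA could leave such a level (log2 difference from the controls -0.11), but 1 value per gene and library cannot tell whether the protein is lost.

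The 9 lists called higher in the libraries labelled KO were those of Sertoli cells, Leydig cells, macrophages, complement, cathepsins, extracellular matrix, cholesterol synthesis, interferon-stimulated genes and the response to TNF and NF-kB, and all 9 calls were lost, with adjusted p = 0.307 to 0.418 with an estimated correlation. Scaling to RPM does not explain their higher levels alone, as with median-of-ratios scaling the mean level of each of the 9 was still 0.31 to 0.86 above that of the controls on the log2 scale (two-sided exact permutation, highest adjusted p = 0.00583). A lower share of germ cells alone would raise the genes of all somatic cell types alike only if germ cells held little of their RNA. The median level over Leydig cell genes was 0.90 higher and that over peritubular genes 0.41 higher. This gap of 0.48 on the log2 scale was the only 1 of 10 pairs of cell types that passed (two-sided exact permutation, adjusted p = 0.0117). The germ cell RNA of the list genes is not known here, and the peritubular list holds Actg2, which fell. The gap therefore cannot decide for or against a lower germ cell share. Without members that fell the gap was 0.45 (adjusted p = 0.0291), but these members were picked by the same comparison, so this is no separate support. With all members the median level of Sertoli cell genes was 0.70 higher, that of endothelial genes 0.50 and that of macrophage genes 0.86. How much a lower germ cell share adds to the higher levels is open, and cell counts or histology were not used here.

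The KO libraries of the 2 title numbers differed in 56 genes (25 higher and 31 lower in number 2). A difference of lines or backgrounds could be shared with the Het library of number 1. In 28 of the 56 genes that library was the most extreme of the 7 controls on the side of the number 1 KO libraries. The next library, WT replicate 3, was so in 12 genes. Het replicate 1 was so in 18 of the 25 genes lower in number 1, but in 10 of the 31 higher in number 1, where WT replicate 3 had 9. A share of 14.3% would hold if each control were equally often the most extreme. The share of Het replicate 1 over all tested genes was not computed, and that library stood apart from the other controls on the second principal component. The count therefore cannot decide for such a difference. Variants carried along with the targeted gene could add genes on chromosome 2, which held 18.2% of the differing genes without Wfdc15a (10 of 55) and 8.40% of all tested genes (one-sided Fisher exact p = 0.0152), of which 5 lay within 20 Mb of Wfdc15a. Chromosome 11 held 8. A difference of batch was not tested, since the number's meaning is not given in the sources used here.

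Among 5 genes named in KO against control the KO libraries of the 2 numbers also differed, by 1.096 for Wfdc15a (SE 0.2292, limma adjusted p = 0.0412), -1.151 for C7 (SE 0.1474, 0.000931), -1.276 for Serping1 (SE 0.2266, 0.0173), -3.004 for Ccl8 (SE 0.4439, 0.00381) and -1.162 for Defb33 (SE 0.2114, 0.0201), number 2 minus number 1 on the log2 scale.

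Of 225 groups of values of named genes, 12 held an outlying library, where the rule gives about 1 in 20 by chance. In Het they were C3 in replicate 3 at 11.56 RPM (next 2.247), Hspb8 in replicate 2 at 12.58 (1.641), 9230104L09Rik in replicate 1 at 3.534 (11.43), Lyz2 in replicate 4 at 25.1 (22.11), Htra1 in replicate 2 at 21.66 (12.5), Wfdc1 in replicate 1 at 12.5 (18.51) and Kdr in replicate 2 at 7.639 (1.685). In KO they were Tnf in replicate 1 at 1.401 (0), Tnni3k in replicate 4 at 1.773 (0.4591), Ctsb in replicate 2 at 359.6 (253.8), Wfdc9 in replicate 4 at 5.096 (10.1) and Klf6 in replicate 6 at 9.641 (15.51). Het replicate 2 holds 3 of the 12.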

How the results depend on the processing

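The separate use of the KO libraries of each title number, limma-voom and the quantile normalization of the lists were chosen after seeing the data. The cause was not tested for any difference below unless the alternative itself shows it.

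KO against control changed 3997 genes. It changed 1549 with title number 2 only and 1931 with the KO libraries of number 2 against all controls (both with fewer libraries), 3592 with those of number 1, and 714 when a change of at least 1 on the log2 scale was asked for. The other settings gave 2992 with quantile normalization to 4024 with library weights, among them 3904 with limma-voom, 3506 with the title number as covariate and 3830 with replicate number as block. The block setting rests on KO replicates 1 to 4. Leaving out a library gave 3259 to 3997.

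KO against WT (1525) gave 1424 with limma-voom and 454 to 1736 when a library was left out, with 454 without WT replicate 1 and 936 without WT replicate 2. KO against Het (3584) gave 3114 and 2668 to 3568. Het against WT gave 0 to 3, with 3 without WT replicate 1. KO number 2 against number 1 (56) gave 23 with a pseudocount of 0.25, 20 without a filter, 40 with limma-voom, 78 with quantile normalization and 11 to 29 when a library was left out: 27 without KO replicate 1, 11 without 2, 18 without 3, 29 without 4, 18 without 5 and 27 without 6. No paired analysis was possible for this comparison, because the sets share no replicate number. In general, replicate numbers did not pair the libraries: same-number pairs correlated at -0.08 to 0.13, and 2 of 11 libraries correlated best with their own number.

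The 12 called lists became 0 with an estimated correlation and 26 with fry, a test without other genes as reference. Lists that fry called higher and camera did not include matrix metalloproteases (fry adjusted p = 0.00053), differentiating spermatogonia (0.00193) and p53 targets and apoptosis (0.000236). Leaving out a library gave 10 to 15, number 2 only 9, median-of-ratios scaling 17 and quantile normalization 15. Called lists were lost with number 2 only (trypsin-like proteases, adjusted p = 0.0565, extracellular matrix 0.0565, complement 0.264) and with KO number 2 only (complement 0.243, extracellular matrix 0.0541). With KO number 1 only interferon-stimulated genes were lost (0.0643), and with quantile normalization round spermatids (0.263). Complement and extracellular matrix were also lost without some single libraries (0.0566 to 0.0639). Fry did not call trypsin-like proteases (0.351), but it does not compare a list with other genes.

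Wfdc15a (-0.66) was at -0.11 with KO number 2 only (exact p = 0.567), -1.21 with KO number 1 only (0.00833), and -0.86 to -0.46 when a library was left out. Of 111 named genes none that passed the test changed sign in these settings. With number 2 only 27 lost their call, among them Sox9 (0.72, adjusted p = 0.0989), C3 (1.15, 0.155), Stra8 (0.56, 0.164), Serping1 (0.54, 0.118) and Ccl8 (0.39, 0.587). With KO number 2 only it was 23 and with median-of-ratios scaling 1, Lck (0.71, 0.0509). Cd68 passed with replicate block (1.28, 0.00232, resting on KO replicates 1 to 4) and with KO number 1 only (1.40, 0.00616). Dpy19l2, Tssk1, H2-Aa and Lck lost their call without some single libraries, with adjusted p up to 0.102.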

Other observations

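The splits of the libraries behind the 5 counts of genes were planned before the results were seen, and the splits for the gene lists were chosen after. The values of lists with quantile normalization or with the KO libraries of 1 title number alone were also chosen after seeing the data, and the other lists and fits were fixed before.

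Each count was compared with the counts from other splits of the same libraries. For KO against control 100 of the 1716 splits were used, the real one and others drawn at random. Only the real split (3997 genes) reached the real count, with 449 genes at most in the others. Chance alone is therefore unlikely, although 1 of 100 is the smallest share this can give. The splits did not hold the title number fixed, so they do not bear on its part in the count. The same held for KO against WT (1 of all 84 splits, 1525 genes, at most 305 in the others). It also held for KO against Het (1 of 100 splits out of 210, 3584 genes, at most 606). For Het against WT all 35 of 35 splits reached the real count of 0, with at most 3. For KO number 2 against number 1 the real split was 1 of 10, with 56 genes and at most 2 in the others, and 10 splits are too few to exclude chance. For the lists 7 of 100 splits called as many as the real 12, with up to 15, so chance cannot be excluded for the number of called lists. That count does not test the single lists. The mean RPM level of each list was also tested over all splits (two-sided exact permutation), a test added to those planned. The called lists other than trypsin-like proteases (adjusted p = 0.269) gave adjusted p = 0.00185 to 0.0144. This argues against chance for their levels, and it does not compare them with other genes.

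Endothelial genes were higher in part in the libraries labelled KO. Of 16 tested genes 5 rose and none fell (6 when adjusted over the list alone, list median 0.39, adjusted p = 0.349), among them the receptor gene Kdr (log2 1.89, SE 0.378) and the cadherin gene Cdh5 (1.57, SE 0.337). Of 10 genes of peritubular and smooth muscle cells 3 rose and 1 fell (5 and 1 when adjusted over the list alone, median 0.48, adjusted p = 0.446). The myosin light chain gene Myl9 rose by 0.60, and the smooth muscle actin gene Actg2 went from 265 to 169 RPM (log2 -0.66, SE 0.0815, adjusted p = 1.23e-05). Of 12 genes of Sertoli cell junctions 3 rose and 1 fell (5 and 1 when adjusted over the list alone, median 0.35, adjusted p = 0.227), with Itgb1 up by 0.99 (SE 0.136), Gja1 up by 0.64 (SE 0.118) and Cldn3, which overlaps another listed gene, at -1.08 (SE 0.200).

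Of 7 MHC class II genes 2 rose and none fell (3 when adjusted over the list alone, median 0.48, adjusted p = 0.299), namely Cd74 (1.68, SE 0.396) and H2-Aa (1.31, SE 0.392), each higher in 5 of the 6 libraries labelled KO. Of 16 cytokines and chemokines 3 rose and none fell (3 when adjusted over the list alone, median 0.24, adjusted p = 0.485). They were Cxcl12 (0.96, SE 0.150), Csf1 (1.54, SE 0.347) and Ccl8 (1.84, SE 0.535, higher in 4 of the 6). Of 9 beta-defensins 2 rose and 1 fell (2 and 2 when adjusted over the list alone, median -0.11, adjusted p = 0.134), with Defb33 going from 31.0 to 13.01 RPM (log2 -1.31, SE 0.222).

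Some lists had too few tested genes for camera. Lcn2, a siderophore-binding protein of neutrophils and epithelia, was the only one of 13 neutrophil genes tested and went from 593 ± 275 RPM (n = 7) to 2006 ± 609 RPM (n = 6, log2 1.82, SE 0.231, adjusted p = 1.48e-05). Of 4 genes of T and NK cells Lck rose (0.83, SE 0.256) and Cd3d fell (-0.87, SE 0.176), by either adjustment. Neither of the 2 mast cell genes, neither of the 2 red blood cell genes and not the 1 tested B cell gene changed, and 1 of 2 epididymis genes rose. None of the 13 mitochondrial genes could be tested.

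Stress genes moved in part. Of 17 genes of the unfolded protein and integrated stress response 8 rose and 1 fell (8 and 1 when adjusted over the list alone, median 0.26, adjusted p = 0.346), with the transcription factor genes Xbp1 up by 0.89 (SE 0.158) and Atf4 by 0.71 (SE 0.125). With median-of-ratios scaling 3 rose and the median was 0.10, and with quantile normalization the list was called higher (adjusted p = 0.0316). Of 17 p53 targets and apoptosis genes 8 rose and 1 fell (8 and 1 when adjusted over the list alone, median 0.59, adjusted p = 0.162). With median-of-ratios scaling 5 rose and 1 fell, and with quantile normalization 3 rose and 2 fell (median 0.29). Among them was the caspase gene Casp8, which rose by 1.36 (SE 0.303). Of 12 immediate early genes 6 rose and none fell (6 when adjusted over the list alone, median 0.63, adjusted p = 0.0524), with Klf6 up by 1.21 (SE 0.196) and Ier2 by 1.05 (SE 0.211). The list was called higher with median-of-ratios scaling (3 rose, adjusted p = 0.0208), quantile normalization (2 rose and 1 fell, 0.0495), replicate number as block (0.0305) and the KO libraries of number 1 alone (0.0321). It was not called with those of number 2 alone (0.198), with title number 2 only (0.264) or with an estimated correlation (0.370). Of 74 ribosomal protein genes 5 rose and 1 fell (1 and 0 when adjusted over the list alone). Their median was 0.01 and their mean 0.04 with camera pointing down (adjusted p = 0.134, and 0.731 with an estimated correlation). With median-of-ratios scaling 2 rose and 5 fell, the median was -0.13 and camera called them (adjusted p = 0.0450). With quantile normalization 2 rose and 5 fell as well, with a median of -0.23 and camera adjusted p = 0.0132.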
